A study of Mus musculus with 39 samples.

How the data were processed

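Poly(A) RNA was extracted with RNeasy Mini Plus columns from PB2 mouse breast tumors and sequenced as 39 directional libraries, per the labels' protocols. PB2 tumors carried FL-HER2 or p95HER2 and were collected 10 or 22 days after implantation, which gives 4 groups (10 FL-HER2 and 10 p95HER2 libraries at day 10, 9 and 10 at day 22). The group of each library was taken from its label, and replicate numbers within a group follow the order of the records and pair nothing. For FL-HER2 day 10 replicate 8 the tumor number differs between the title and the description, and the description names its column. This number has 5 digits in 8 of the 10 FL-HER2 day 10 libraries and 3 elsewhere, so a term for it beside the group rests on the other 2.

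Reads were aligned with STAR 2.4.2a to the mm10 build, and DESeq2 was used, per the submitters' processing notes. The read counter, the gene annotation, the strand setting and any filter are not given in the sources used here. The deposited table holds 1 value for each of 20520 genes and 39 libraries. Its name says CPM, but the values fit log2(read count / size factor + 1), as found from the values: after undoing the log2, 100% of them were whole multiples of 1 step per library (tolerance 0.001 reads, highest distance 2.70e-08). The authors' deposited log2 values are therefore normalized by 1 factor per library, and the totals of normalized counts still run from 26873201 to 32123851. The plan fixed before the data were examined assumed CPM, so the log2 values were used as deposited, with their built-in pseudocount of 1.

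Whole reads were recovered by dividing by the step, which gave 21772259 to 44427621 reads per library, and CPM was computed from them for levels and filters. At this depth 1 CPM stands for more than 20 reads in each library, and spread between libraries rather than counting sets most errors. Y-linked and mitochondrial genes were not analysed here. Counting on genes can divide or lose reads between near-identical paralogs, and reads of a construct fall to Erbb2 as far as they align to it. No 2 libraries had identical values.

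Genes with at least 1 CPM in at least 9 libraries were tested, 13650 in all. A linear model with 1 coefficient per group over all 39 libraries was fitted to the log2 values with limma 3.58.1 (lmFit, contrasts.fit, eBayes with a trend) in R 4.3.3, two-sided. Its 5 contrasts were p95HER2 against FL-HER2 at day 10 and at day 22, day 22 against day 10 in each construct, and the change of the p95HER2 effect between days. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 per contrast. Principal components and list scores (the mean log2 value of a list's members) used the same values. Gene positions are those of the GENCODE M21 annotation of GRCm38, the assembly behind mm10, and 13530 of the 13650 tested genes (99.1%) matched 1 gene by symbol.

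Before the data were examined, 56 gene lists were written for pathways, tumor cell states, immune and stromal cells and tissues that could lie next to a tumor. Of their 971 genes 919 were in the table, and 51 lists had at least 3 tested members. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 51 lists, and again with an estimated correlation and with fry. A permutation test of the mean list score was added after seeing the data (two-sided, exact between 2 groups, 100000 resamples for the change between days). Counts of members called are given over all genes tested and with p-values adjusted over the list alone.

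The genes named were chosen by a rule fixed before the data were examined. It takes up to 5 of the largest rises and falls per contrast among called genes that have at least 5 CPM in the higher group and a difference of medians of the same sign and at least 0.5 of the log2 change, leaving out predicted genes, clones and immunoglobulin or T cell receptor segments. It adds, from each list it takes, 2 to 4 members with the smallest adjusted p, and for a list with no member called up to 2 of the highest mean CPM. Erbb2 and Cd274 are always given. It takes a list when camera calls it, when at least 3 members are called, or when it marks a contaminating tissue that moves. Some genes, and many lists without a camera call, that this rule takes are not reported here.

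Other settings chosen before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter at 5 CPM, median-of-ratios size factors, quantile normalization, a fit on only the groups compared, library weights, a rank-sum test per gene, a log2 change of at least 1, and leaving out each library. Settings chosen after seeing the data were log2(CPM + 1), voom on the recovered reads, the muscle list score of each library as a covariate, only libraries with 0.1% to 1.3% of reads in the muscle list (called muscle-limited), only libraries with a mean log2 value of the tested skin list members below 6 (8 and 5, 8 and 7), and the number of digits in the column name as a term beside the group. The planned count-based tests were not run, since tests of that kind were kept to values deposited on a linear scale, and voom was run on the recovered reads instead. For the count of genes called in each contrast, 100 splits of the libraries, the real one included, were fitted.

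The fit was tested on simulated data of 13650 genes with 200 changed. Per contrast it recovered 53.7% to 77.6% of log2 changes of 0.5, 83.6% to 94.0% of those of 1 and 92.4% to 98.5% of those of 2. It called 6 to 13 unchanged genes, no bound for the real libraries, whose other splits called up to 4183.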

Results

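The series profiled PB2 mouse breast tumors, grown as grafts, that carried either full-length HER2 (FL-HER2) or p95HER2, the truncated receptor that lacks most of the extracellular domain. Tumors were taken 10 or 22 days after implantation, and poly(A) RNA was sequenced in directional libraries. The 39 libraries fell into 4 groups: 10 of FL-HER2 at day 10, 9 of FL-HER2 at day 22, 10 of p95HER2 at day 10 and 10 of p95HER2 at day 22. Each column name holds a number, of 5 digits in 8 FL-HER2 day 10 libraries and of 3 in all others. The 5 digits can be read as tumor numbers run together, so these may be pools. The sources used here do not say whether each library is 1 tumor or tumors came from separate animals. The p-values thus measure the spread between these samples, which may be technical. The values cover 20520 mouse genes, written as log2 of the normalized count plus 1. Whole reads recovered from them came to 21772259 to 44427621 per library (mean 34009091 ± 3708309, SD, n = 39). Of these genes, 13650 had a CPM of at least 1 in at least 9 libraries and were tested. Changes are log2 changes, given ± SE from the fit for single genes, and CPM is mean ± SD. For gene lists, counts and medians cover the members, and camera p-values, with the preset correlation and, marked estimated, with an estimated one, are adjusted.

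The libraries differed in skeletal muscle RNA. The 20 members of the muscle marker list, such as Myh4 and Ckm, took 1.86% ± 1.13 of reads in FL-HER2 at day 10 (SD, n = 10, range 0.0503% to 3.82%), 0.336% ± 0.273 in FL-HER2 at day 22 (n = 9), 0.316% ± 0.407 in p95HER2 at day 10 (n = 10, range 0.00355% to 1.04%) and 0.207% ± 0.200 in p95HER2 at day 22 (n = 10). The group with the highest mean share, FL-HER2 at day 10, enters 3 of the 5 comparisons. Libraries with 0.1% to 1.3% muscle reads (3 FL-HER2 and 4 p95HER2 at day 10, 8 and 6 at day 22) are called muscle-limited. They are not matched in muscle, with list medians of -1.87 and -1.26 with time in FL-HER2 and p95HER2 and of -0.58 and 0.07 between constructs at days 10 and 22.

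In FL-HER2 at day 10 the 2 libraries with 3-digit numbers, replicates 7 and 9, had muscle shares of 1.14% and 2.17%, within the range of the 8 with 5 digits. Between the 2 and the 8, 93 genes differed (34 higher and 59 lower with 5 digits, and 2180 at an unadjusted p under 0.05). Camera called 11 lists in this split, among them type I interferon (median -1.46), interferon gamma (-1.71) and MHC class I (-1.13), lower with 5 digits, and matrix (0.70), fibroblasts (0.61) and endothelium (0.45), higher, all with adjusted p of at least 0.632 with an estimated correlation. After seeing the data, the comparisons were repeated with the number of digits as a term beside the group, which leaves the level of FL-HER2 at day 10 to those 2 libraries. With it, 23 of 26 type I interferon members were lower in p95HER2 at day 10 (median -1.74; 4 and -0.51 without it) and 21 fell with time in FL-HER2 (-1.49; 2 and -0.40 without it).

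Skin markers set 11 libraries apart, most low in muscle. The mean log2 value of the 7 tested skin list members was 7.02 to 10.4 in these and 4.24 to 5.81 in the other 28. They were FL-HER2 replicates 7 and 10 at day 10 and 7 at day 22, and p95HER2 replicates 2, 3, 7, 8 and 9 at day 10 and 3, 4 and 10 at day 22. Repeats of the comparisons without these skin-high libraries thus also drop low-muscle ones.

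**Figure D1:**
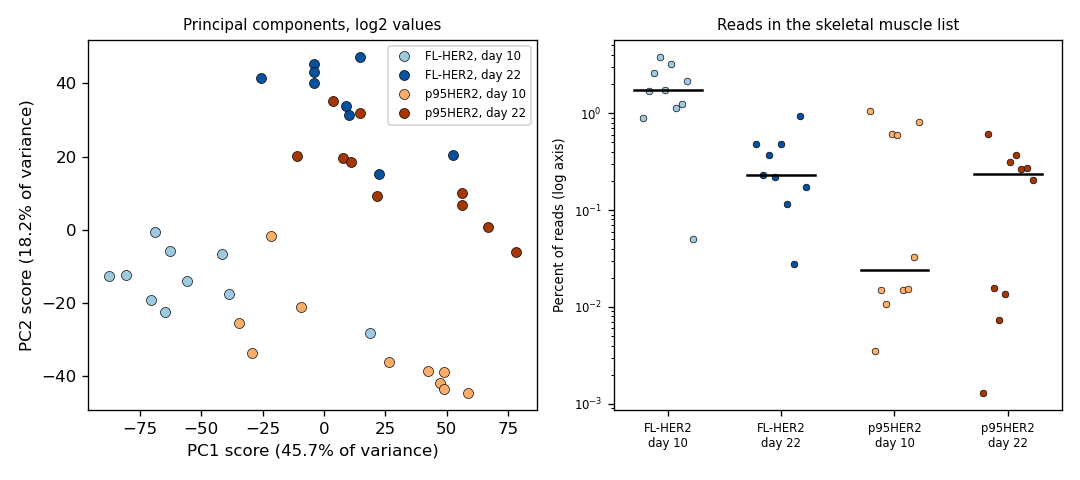
Left, scores of the 39 libraries on the first (45.7% of variance) and second (18.2%) principal components of the log2 values, colored by group. Right, percent of reads in the skeletal muscle list for each library on a log axis, with a line at each group's median. FL-HER2 day 10 libraries reach 3.82%, and p95HER2 day 10 libraries spread from 0.00355% to 1.04%.

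Erbb2, the mouse gene for HER2, was higher in p95HER2 than in FL-HER2 tumors at both times. Its level was 184 ± 29.4 CPM in FL-HER2 and 346 ± 62.3 CPM in p95HER2 at day 10 (n = 10 each, log2 change 0.85 ± 0.10, adjusted p = 6.63e-08). At day 22 it was 113 ± 25.2 (n = 9) and 185 ± 26.3 CPM (n = 10, 0.73 ± 0.11, adjusted p = 1.41e-05). Erbb2 fell with time in FL-HER2 (-0.84 ± 0.11, adjusted p = 3.04e-08) and in p95HER2 (-0.96 ± 0.10, adjusted p = 1.59e-09), and the difference between the constructs did not pass the test of a change between days (-0.12 ± 0.15, adjusted p = 0.608). In the mm10 build Erbb2 lies on chromosome 11, 98412470 to 98437716, plus strand. The value is a sum over the gene, and reads of the construct and of the endogenous gene were not separated. Cd274, which encodes the checkpoint ligand PD-L1, ranged widely: 29.0 ± 25.1 and 17.3 ± 14.7 CPM at day 10, and 15.9 ± 4.43 and 10.3 ± 5.06 CPM at day 22, in FL-HER2 and p95HER2. It passed none of the 5 tests: its change was -0.65 ± 0.43 and -0.73 ± 0.44 between constructs at days 10 and 22 (adjusted p = 0.227 and 0.405), -0.49 ± 0.44 and -0.57 ± 0.43 with time in FL-HER2 and p95HER2 (0.360 and 0.319), and -0.08 ± 0.61 for the change between days (0.941), all within the spread between libraries.

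**Figure D2:**
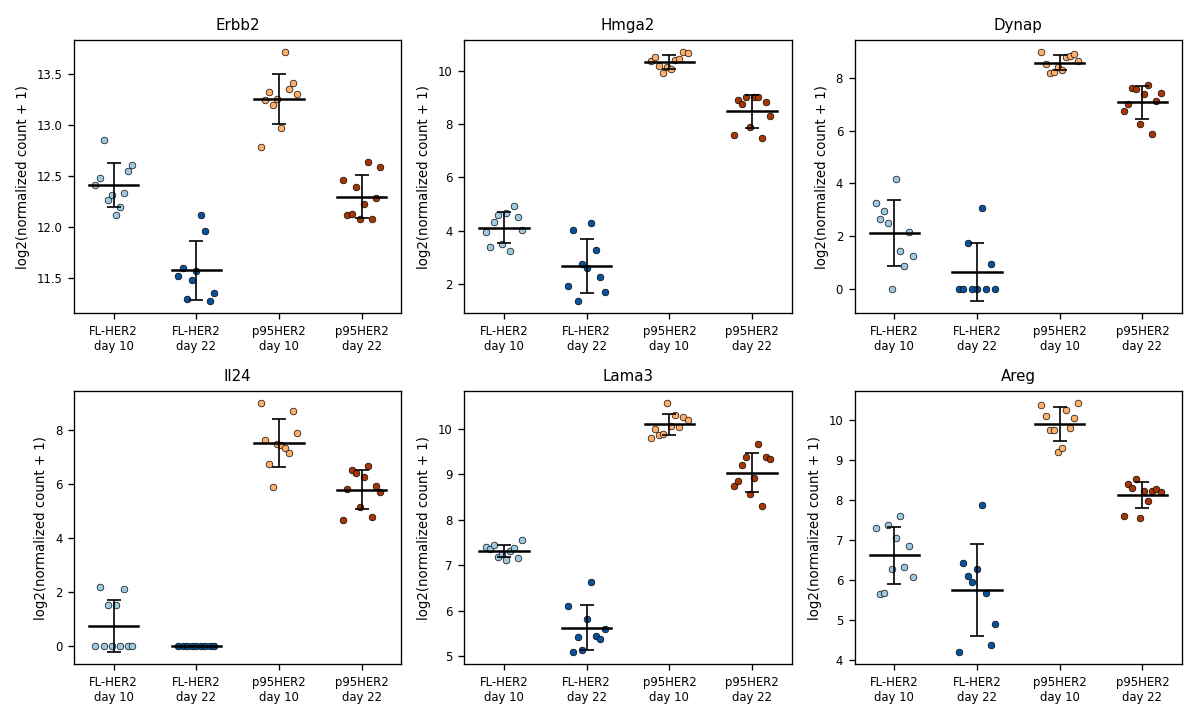
Log2(normalized count + 1) of 6 genes in each library, by group, with the mean (line) and SD (bars). Hmga2, Dynap, Lama3 and Il24 sit higher in every p95HER2 library than in any FL-HER2 library of the same day, and the Erbb2 groups differ by 0.85 and 0.73.

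The first comparison asked how p95HER2 tumors differed from FL-HER2 tumors 10 days after implantation. A small set of genes that were close to absent in FL-HER2 tumors was expressed in p95HER2 tumors, targets of MAPK signaling and the EGF receptor ligands Hbegf and Areg were higher, and fibroblast, macrophage, endothelial and skeletal muscle markers were lower. Of these list calls, that of the MAPK targets held with an estimated correlation. Hmga2, a chromatin architectural protein of embryonic tissues, went from 0.584 ± 0.226 CPM in FL-HER2 to 45.2 ± 7.78 CPM in p95HER2 (SD, n = 10 each, log2 change 6.21 ± 0.29, adjusted p = 1.18e-19). Il24, a cytokine of the IL-10 family, rose from 0.0344 ± 0.0480 to 7.48 ± 4.69 CPM (6.79 ± 0.35, adjusted p = 3.35e-18), with 6 of 10 FL-HER2 libraries listed at 0. Dynap, a dynactin-associated membrane protein, rose from 0.162 ± 0.162 to 13.5 ± 2.62 CPM (6.46 ± 0.39, adjusted p = 4.82e-16). Mmp10, a matrix protease, and Msln, a surface glycoprotein, completed the 5 largest rises (5.11 ± 0.43 and 3.57 ± 0.51). Hmga2 lies on chromosome 10, 120361275 to 120476469, minus strand, Il24 on chromosome 1, 130882074 to 130887454, minus strand, and Dynap on chromosome 18, 70240429 to 70244582, minus strand (mm10). These changes are on the log2(normalized count + 1) scale, which understates those of genes near 0.

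Of 13650 genes, 5636 (41.3%) changed at day 10: 2071 were higher and 3565 lower in p95HER2, and 1010 did so by at least 2-fold (112 higher, 898 lower). The split depended on the scaling, with 36.7% of the calls higher on the deposited values, 49.1% with median-of-ratios size factors, 62.9% after quantile normalization and 51.5% on log2(CPM + 1). The median log2 change of all tested genes was -0.0412 on the deposited values and 0.0641 after quantile normalization. The 5 largest falls were in genes of striated muscle: Myh7 (-5.94 ± 1.62, adjusted p = 0.00334), Myh4 (-5.53 ± 1.38, adjusted p = 0.00146), Ckm (-5.39 ± 1.34, adjusted p = 0.00146), Ckmt2 (-5.33 ± 1.15, adjusted p = 0.000304) and Pvalb (-5.26 ± 1.36, adjusted p = 0.00206). All 20 skeletal muscle members fell (20 adjusted over the list alone). Skeletal muscle markers had a median of -4.36 (camera adjusted p = 8.53e-06, 0.564 estimated). With the muscle score of each library as a covariate, 3242 genes changed, and 2952 of the 5636 (52.4%) kept their call and sign. The falls of Myh7, Myh4, Ckm and Pvalb did not pass that fit, where their log2 changes were 0.18, -0.08, -0.08 and 0.11, nor a fit without the 11 skin-high libraries. Among muscle-limited libraries 641 genes were called, and with the digits as a term 1375, where 5330 of the 5636 (94.6%) kept their direction.

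Among signaling and epithelial groups at day 10, 13 of 18 members rose (13 adjusted over the list alone) in the MAPK feedback list, genes that ERK signaling induces, some of which restrain it. MAPK feedback targets had a median of 0.34 (camera adjusted p = 4.42e-08, 0.0413 estimated). They included Fosl1, an AP-1 subunit (2.22 ± 0.25), the ERK phosphatases Dusp5 (1.03 ± 0.12) and Dusp4 (1.34 ± 0.17), and the receptor Epha2 (0.56 ± 0.07), each with adjusted p of at most 2.97e-07. In the list of HER2 family receptors and ligands, 6 of 12 members rose and 2 fell (6 and 2 adjusted over the list alone). For HER2 family genes the median was 0.21 (camera adjusted p = 0.0306, 0.506 estimated). The EGF receptor ligands Hbegf (1.81 ± 0.17) and Areg (3.27 ± 0.30) rose with Erbb2, and Egf, which muscle also expresses, fell (-2.003 ± 0.40), a call that ended with the muscle score as a covariate (-0.66, adjusted p = 0.0739). Of basal and myoepithelial markers, 4 of 14 members rose (4 adjusted over the list alone), among them the integrin Itgb4 (0.68 ± 0.07) and the desmosomal cadherin Dsg3 (1.92 ± 0.31). Basal markers had a median of 0.13 (camera adjusted p = 0.0190, 0.564 estimated). The skin list genes, which summed to 156 ± 201 CPM in FL-HER2 and 154 ± 165 CPM in p95HER2, had 1 of 7 members lower (median 0.42, camera adjusted p = 0.983), and 3 basal members rose without the skin-high libraries (median 0.07). Of cholesterol synthesis genes, 14 of 23 members rose (15 higher and 1 lower adjusted over the list alone), among them Hsd17b7 (0.57 ± 0.11). Cholesterol synthesis genes had a median of 0.27 (camera adjusted p = 5.52e-06, 0.564 estimated). Of ribosomal protein genes, 9 of 24 members rose (9 adjusted over the list alone), with small changes such as Rps4x (0.20) and Rps6 (0.17). For ribosomal protein genes the median was 0.11 (camera adjusted p = 4.75e-05, 0.564 estimated). Of p53 targets, 7 of 20 members rose and 1 fell (7 and 2 adjusted over the list alone), including Zmat3 (0.47) and Mdm2 (0.37). Targets of p53 had a median of 0.09 (camera adjusted p = 0.0429, 0.528 estimated). The muscle markers took 1.86% ± 1.13 of reads in FL-HER2 and 0.316% ± 0.407 in p95HER2 (SD, n = 10 each). The calls of the HER2 family, basal and p53 lists ended under 6, 2 and 3 alternatives (camera adjusted p 0.000465 to 0.158, 0.00539 to 0.0778 and 0.00635 to 0.0976 over the alternatives). Among the muscle-limited libraries, the HER2 family list had a median of -0.12 and cholesterol synthesis one of 0.07 (camera adjusted p 2.26e-07 to 0.158 over the alternatives, the highest in these libraries).

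Camera called stromal and myeloid lists lower in p95HER2 tumors at day 10. Of fibroblast markers, 18 of 24 members fell (21 adjusted over the list alone), such as the proteoglycans Ogn (-2.40 ± 0.27) and Dcn (-1.66 ± 0.21), the surface protein Cd34 (-1.37 ± 0.15) and the microfibril protein Mfap5 (-1.62 ± 0.19). Fibroblast markers had a median of -1.14 (camera adjusted p = 2.97e-08, 0.528 estimated). In the extracellular matrix list 6 of 30 members rose and 19 fell (6 and 21 adjusted over the list alone): collagen Col3a1 (-1.54) and Sparc (-1.04) fell, and the basement membrane genes Lamb1 (0.66) and Col18a1 (1.02) rose. For matrix genes the median was -0.72 (camera adjusted p = 0.0209, 0.815 estimated). Of macrophage markers, 16 of 21 members fell (17 adjusted over the list alone), among them Gpnmb (-1.47 ± 0.20), the F4/80 gene Adgre1 (-1.12 ± 0.16) and the lipid receptor Trem2 (-0.80 ± 0.12). Macrophage markers had a median of -0.73 (camera adjusted p = 4.16e-06, 0.528 estimated). Of complement genes, 15 of 17 members fell (15 adjusted over the list alone), including the anaphylatoxin receptor C3ar1 (-0.98) and the regulator Cd55 (-1.14). Complement genes had a median of -0.78 (camera adjusted p = 3.42e-05, 0.528 estimated). Of endothelial markers, 1 of 26 members rose and 15 fell (1 and 16 adjusted over the list alone), among them Clec14a (-1.58 ± 0.25), the angiopoietin receptor Tek (-1.33 ± 0.21) and Eng (-0.75 ± 0.13). For endothelial markers the median was -0.48 (camera adjusted p = 0.00288, 0.629 estimated). Of adipocyte genes, 1 of 17 members rose and 9 fell (3 and 11 adjusted over the list alone), with lipoprotein lipase Lpl (-1.75) and the lipid droplet protein Plin4 (-2.98) among the falls. Adipocyte genes had a median of -1.03 (camera adjusted p = 0.0429, 0.564 estimated). Of oxidative phosphorylation genes, which muscle (1.86% and 0.316% of reads) expresses strongly, 21 of 22 members fell (21 adjusted over the list alone), including Sdhb (-0.58) and Ndufb8 (-0.38). Oxidative phosphorylation genes had a median of -0.27 (camera adjusted p = 3.13e-06, 0.528 estimated). Among the muscle-limited libraries, the matrix, complement, endothelial and oxidative phosphorylation calls ended (camera adjusted p 9.81e-05 to 0.183, 1.67e-07 to 0.0683, 0.000311 to 0.864 and 1.26e-09 to 0.0899 over the alternatives), and the adipocyte call ended under 3 others (0.00140 to 0.120). In these libraries, of which 1 of 3 FL-HER2 and 0 of 4 p95HER2 were skin-high, camera called the skin list lower (2 of 7 members, median -2.35). With the digits as a term the matrix and endothelial calls ended, at medians of -0.08 and -0.11. Of the 45 genes named for day 10 that passed, 24 did not pass in these libraries, and 20 did not under at least 1 other alternative.

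**Figure D3:**
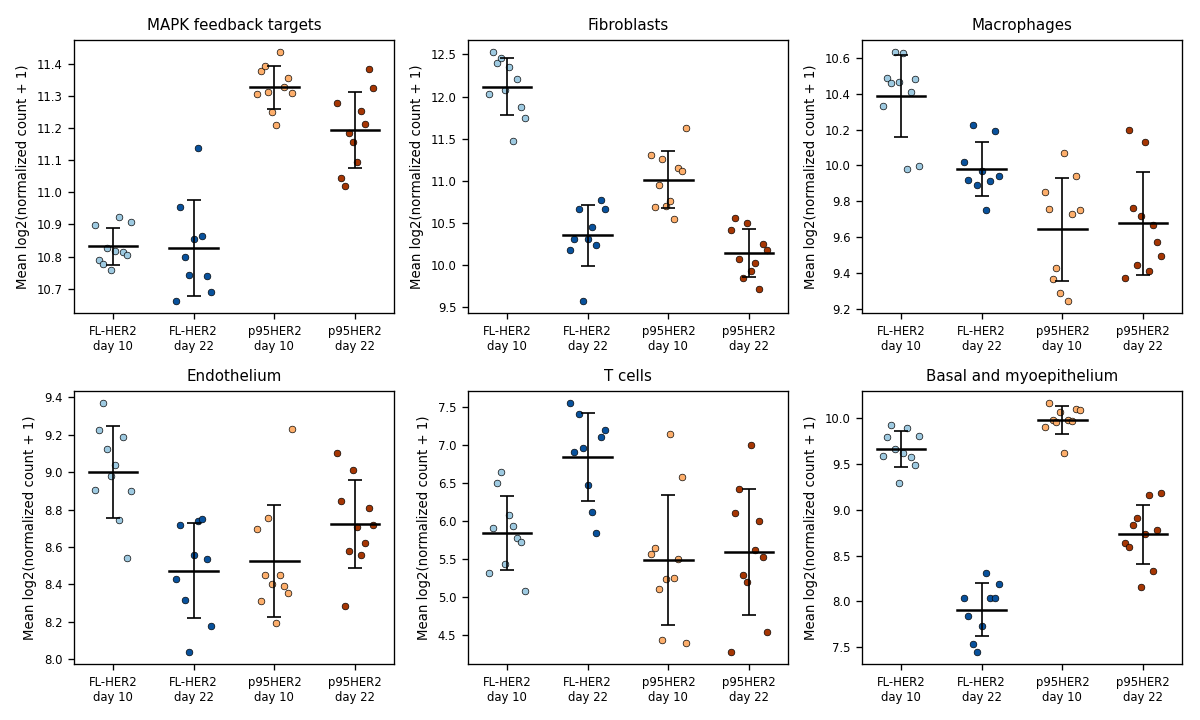
Mean log2(normalized count + 1) over the members of 6 gene lists in each library, by group, with the group mean (line) and SD (bars). The fibroblast score is lower at day 22 than at day 10 in both constructs, and the T cell score is highest in FL-HER2 at day 22 (6.84 ± 0.580, SD, n = 9).

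At day 22 the same question gave fewer differences. The genes near 0 in FL-HER2 tumors stayed expressed in p95HER2 tumors, basal epithelial genes and MAPK targets were higher, and T cell and MHC class II genes were lower. The basal and MAPK calls held with an estimated correlation, and the T cell and MHC class II calls did not. Dynap was at 5.24 ± 1.87 CPM in p95HER2 (SD, n = 10) against 0.0441 ± 0.0917 CPM in FL-HER2 (n = 9, log2 change 6.43 ± 0.40, adjusted p = 2.03e-15), and Hmga2 at 13.9 ± 5.01 against 0.259 ± 0.225 CPM (5.79 ± 0.29, adjusted p = 3.72e-18). Lama3, the alpha chain of laminin-332, stood at 19.7 ± 5.44 against 1.87 ± 0.780 CPM (3.41 ± 0.16, adjusted p = 1.84e-19). The ligand Areg (2.37 ± 0.31, adjusted p = 1.42e-06) and the cGMP-dependent kinase Prkg2 (2.20 ± 0.18, adjusted p = 1.77e-11) completed the 5 largest rises. The largest falls were in genes of immune cells: the class I-like molecule H2-m2 (-3.10 ± 0.72, adjusted p = 0.00812), Ly6i (-2.28 ± 0.67, 0.0381), the nuclease Dnase1l3 (-2.12 ± 0.60, 0.0331), Slamf8 (-1.90 ± 0.47, 0.0138) and the T cell receptor chain Cd3g (-1.77 ± 0.50, 0.0336). Of 13650 genes, 617 (4.52%) changed, 407 higher and 210 lower in p95HER2, of which 128 by at least 2-fold (66 higher, 62 lower). The count rests in part on single libraries: it was 339, 370 and 411 without FL-HER2 day 22 replicate 1, 3 or 8, and 408, 405 and 355 without p95HER2 day 22 replicate 4, 9 or 10, and 228 without the 1 FL-HER2 and 3 p95HER2 skin-high libraries. With library weights it was 1418, by the rank-sum test 267, and among muscle-limited libraries 252. Removing 1 library ended the call of Ly6i for 11 of the libraries, of Dnase1l3 for 10 and of Cd3g for 10 (adjusted p up to 0.0917, 0.0848 and 0.0878).

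Camera called lymphoid and antigen presentation lists lower in p95HER2 tumors at day 22, and none of these calls held with an estimated correlation. Of T cell genes, 12 of 21 members fell (18 adjusted over the list alone), such as the transcription factor Bcl11b (-1.33 ± 0.26), the costimulatory receptor Icos (-2.07 ± 0.41), Cd4 (-1.23 ± 0.28) and Cd5 (-1.49 ± 0.35), with adjusted p of at most 0.00851. For T cell genes the median was -1.43 (camera adjusted p = 7.81e-13, 0.187 estimated). Of regulatory T cell genes, 3 of 9 members fell (1 higher and 6 lower adjusted over the list alone), led by the lineage factor Foxp3 (-1.68 ± 0.30) and the checkpoint receptor Ctla4 (-1.66 ± 0.43). Regulatory T cell genes had a median of -1.01 (camera adjusted p = 0.000305, 0.187 estimated). Of cytotoxic and NK cell genes, 2 of 13 members fell (11 adjusted over the list alone), namely Ccl5 (-1.50) and Klrk1 (-1.44). Cytotoxic and NK cell genes had a median of -1.45 (camera adjusted p = 2.09e-06, 0.300 estimated). Of MHC class II genes, 6 of 9 members fell (9 adjusted over the list alone), including H2-ab1 (-1.26 ± 0.32) and H2-eb1 (-1.26 ± 0.33). For MHC class II genes the median was -1.09 (camera adjusted p = 5.16e-08, 0.187 estimated). In the interferon gamma list 1 of 26 members fell (1 adjusted over the list alone), Ciita, the class II transactivator (-1.09 ± 0.31), with Irf8 next (-0.81, adjusted p = 0.0737), and 18 had an unadjusted p under 0.05. Interferon gamma genes had a median of -0.99 (camera adjusted p = 3.40e-09, 0.443 estimated). The type I interferon list had 11 of 26 members at an unadjusted p under 0.05, with values such as Oasl2 (-0.60 ± 0.27, adjusted p = 0.221). Type I interferon genes had a median of -0.59 (camera adjusted p = 3.96e-07, 0.517 estimated). The MHC class I list had 2 of 17 such members, and its most abundant were B2m (-0.31, adjusted p = 0.635) and H2-k1 (-0.24, 0.717). For MHC class I genes the median was -0.34 (camera adjusted p = 0.00113, 0.614 estimated). Of dendritic cell genes, 3 of 15 members fell (5 adjusted over the list alone), with Itgae (-1.44) and Wdfy4 (-0.58). Dendritic cell genes had a median of -0.50 (camera adjusted p = 9.56e-05, 0.187 estimated). Of macrophage markers, 4 of 21 members fell (1 higher and 7 lower adjusted over the list alone), with Gpnmb (-0.82) and Mertk (-0.44). Macrophage markers had a median of -0.31 (camera adjusted p = 4.08e-05, 0.374 estimated). The T cell and regulatory T cell calls ended when only genes with at least 5 CPM in 9 libraries were tested (camera adjusted p 1.59e-16 to 0.101 and 3.52e-05 to 0.774 over the alternatives, the highest there), and the MHC class I call ended with the muscle score as a covariate (4.16e-07 to 0.0607). Leaving out 1 library brought Irf8 past the test for 4 libraries and ended the call of Ccl5 for 7 libraries, Klrk1 for 12, Ciita for 9 and Wdfy4 for 6, that of Mertk without FL-HER2 day 22 replicate 1 or p95HER2 day 22 replicate 7 (adjusted p up to 0.0781), and that of H2-eb1 without p95HER2 day 22 replicate 10 (0.0535).

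Camera called epithelial and signaling lists higher in p95HER2 tumors at day 22. Of basal and myoepithelial markers, 7 of 14 members rose (8 adjusted over the list alone), among them Dsg3 (3.37 ± 0.32) and the keratins Krt17 (1.14 ± 0.19) and Krt6a (2.55 ± 0.44). For basal markers the median was 0.55 (camera adjusted p = 1.39e-12, 0.0135 estimated). The skin list stood at 44.9 ± 8.88 CPM in FL-HER2 (n = 9) and 73.3 ± 48.7 CPM in p95HER2 (n = 10), with 0 of 7 members past the test in limma and 1 at an unadjusted p under 0.05 (median 0.57, camera adjusted p = 0.113). Without the skin-high libraries 5 basal members rose (median 0.52). Of MAPK feedback targets, 8 of 18 members rose (9 adjusted over the list alone), including Fosl1 (2.43 ± 0.25), Emp1 (0.47 ± 0.09) and Epha2 (0.41 ± 0.08). MAPK feedback targets had a median of 0.20 (camera adjusted p = 1.60e-07, 0.0257 estimated). Of HER2 family genes and ligands, 3 of 12 members rose (4 adjusted over the list alone), which were Hbegf (1.42 ± 0.17), Areg (2.37 ± 0.31) and Erbb2. HER2 family genes had a median of 0.16 (camera adjusted p = 0.000118, 0.0257 estimated). In the TGF-beta list 4 of 17 members rose (5 higher and 1 lower adjusted over the list alone), led by the activin subunit Inhba (1.56 ± 0.16) and Thbs1 (0.55 ± 0.11). For TGF-beta genes the median was 0.11 (camera adjusted p = 0.000490, 0.187 estimated). Of inflammatory cytokine genes, 4 of 15 members rose and 1 fell (5 and 1 adjusted over the list alone), with Il23a (1.61 ± 0.29) and Ptgs2, which makes prostaglandins (0.86 ± 0.19), among the rises. Inflammatory cytokine genes had a median of 0.24 (camera adjusted p = 0.00464, 0.392 estimated). Of luminal markers, 2 of 20 members rose (3 adjusted over the list alone), the keratin Krt7 (1.32 ± 0.16) and Tfap2c (0.24). Luminal markers had a median of 0.14 (camera adjusted p = 0.00206, 0.187 estimated). Of hypoxia genes, 3 of 23 members rose (3 adjusted over the list alone), such as Car9 (0.47 ± 0.10) and P4ha1 (0.39 ± 0.09). For hypoxia genes the median was 0.20 (camera adjusted p = 9.56e-05, 0.392 estimated). In the Notch list 2 of 13 members rose (2 adjusted over the list alone), the ligands Jag1 (0.76 ± 0.13) and Dll4 (0.48). Notch genes had a median of 0.10 (camera adjusted p = 0.0327, 0.251 estimated). Of endothelial markers, 1 of 26 members rose (1 adjusted over the list alone), Emcn (0.63 ± 0.16), with Tie1 next (0.41, adjusted p = 0.0873). Endothelial markers had a median of 0.25 (camera adjusted p = 2.17e-05, 0.443 estimated). The muscle list had a median log2 change of -1.86 and 1 of 20 members at an unadjusted p under 0.05 (camera adjusted p = 0.000118, adjusted p = 0.602 with an estimated correlation). The muscle call ended with the muscle score as a covariate, where its median was 0.03. The Notch and inflammatory cytokine calls ended under 2 and 3 alternatives (camera adjusted p 0.0134 to 0.140 and 0.000812 to 0.108 over the alternatives). Leaving out 1 library ended the call of Tfap2c for 9 libraries, Dll4 for 6 and Emcn without FL-HER2 day 22 replicate 1 or 9 (adjusted p up to 0.0522).

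Further lists that camera called at day 22 had small medians. Proliferation (-0.09, camera adjusted p = 0.000490) and MYC target genes (-0.07, 0.00317) were lower, with adjusted p = 0.532 and 0.392 with an estimated correlation, and 4 of 30 and 4 of 20 members had an unadjusted p under 0.05. Of immediate early genes, 1 of 15 members rose (3 adjusted over the list alone), Egr1 (0.53 ± 0.14), with Junb next (0.32, adjusted p = 0.0646). For immediate early genes the median was 0.18 (camera adjusted p = 0.00838, 0.475 estimated). Of Wnt targets, 3 of 15 members rose (3 adjusted over the list alone), including Sfrp1 (0.35 ± 0.08) and Lgr5 (0.68). Wnt targets had a median of 0.10 (camera adjusted p = 0.0227, 0.425 estimated). Of matrix genes, 2 of 30 members rose (6 adjusted over the list alone), Col18a1 (1.01 ± 0.14) and Fn1 (0.66 ± 0.14). Matrix genes had a median of 0.05 (camera adjusted p = 0.0386, 0.710 estimated). Of pericyte and smooth muscle markers, 1 of 13 members rose (1 adjusted over the list alone), the potassium channel Kcnj8 (0.69 ± 0.20), with Abcc9 next (0.32, adjusted p = 0.312). For pericyte markers the median was 0.18 (camera adjusted p = 0.0361, 0.517 estimated). Of plasma cell genes, 1 of 3 members rose (1 adjusted over the list alone), Sdc1, a proteoglycan that epithelium also makes (0.48 ± 0.08), with Prdm1 next (0.09, adjusted p = 0.836). Plasma cell genes had a median of 0.34 (camera adjusted p = 0.0390, 0.187 estimated). The matrix and plasma cell calls each ended under 5 alternatives and the Wnt and pericyte calls under 1 (camera adjusted p 0.00587 to 0.127, 0.0193 to 0.126, 0.00434 to 0.0639 and 0.00460 to 0.0724 over the alternatives). Leaving out 1 library ended the call of Egr1 for 8 libraries, Lgr5 for 10 and Kcnj8 for 11, and brought Junb past the test without FL-HER2 day 22 replicate 6 or 8 (adjusted p = 0.0346 and 0.0437). Of the 51 genes named for day 22 that passed, the rank-sum test ended 23 calls, H2-m2, Slamf8 and H2-ab1 among them (adjusted p up to 0.141), the restriction to muscle-limited libraries 23 (up to 0.319) and the muscle score as a covariate 11. Without the skin-high libraries 16 of these calls ended, among them those of Cd3g, Cd4, Ctla4, H2-eb1 and Ptgs2.

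The p95HER2 effects at the 2 times, which share no library, overlapped. Of the genes called at both, 210 were higher at both (61.8 if the calls were independent) and 98 lower (54.8). Another 10 were higher then lower (31.9) and 23 the reverse (106). The 308 that went the same way ranged from 85 (muscle-limited) to 626 (library weights). A line or batch difference that goes with the construct would recur too and cannot be told apart.

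The next comparison followed FL-HER2 tumors from day 10 to day 22. Fibroblast, matrix, mesenchymal, basal epithelial and vascular genes fell, and proliferation, T cell and MHC class II genes rose, list calls of which none held with an estimated correlation. The largest rises were in Dcpp3 (5.57 ± 0.56, adjusted p = 1.28e-10), Dcpp1 (5.48 ± 0.48, 6.02e-12) and Dcpp2 (5.22 ± 0.61, 4.09e-09), near-identical secreted proteins of salivary gland that neighbor each other on chromosome 17, so how reads divide among them is uncertain. They were followed by H2-m2 (4.86 ± 0.72, 6.13e-07) and the connexin Gjc3 (4.05 ± 0.28, 1.91e-14). The largest falls were in the tenascin Tnn, from 28.8 ± 13.4 to 1.37 ± 0.724 CPM (-4.53 ± 0.50, 1.43e-09), the keratin Krt6a (-4.28 ± 0.44, 2.63e-10), the cartilage matrix protein Chad (-4.26 ± 0.41, 5.86e-11), Wfdc12 (-3.88 ± 0.36, 2.55e-11) and Dlk1, an inhibitor of adipocyte differentiation (-3.83 ± 0.43, 2.06e-09). In all, 7011 genes (51.4%) changed, 2830 higher and 4181 lower at day 22, and 1445 by at least 2-fold (202 higher, 1243 lower). The share of higher calls was 40.4% on the deposited values, 62.5% after quantile normalization and 62.4% on log2(CPM + 1). All tested genes had a median log2 change of -0.0331, 0.0794 and 0.0795 on the deposited values, after quantile normalization and on log2(CPM + 1). Among muscle-limited libraries 3506 genes were called, and with the digits as a term 2953, where 6760 of the 7011 (96.4%) kept their direction and 9 of the 49 genes named here that passed lost their call.

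Camera called stromal lists lower with time in FL-HER2 tumors. Of fibroblast markers, 23 of 24 members fell (23 adjusted over the list alone), with Postn (-2.29 ± 0.16) and Col1a1 (-2.57 ± 0.19) among them. Fibroblast markers had a median of -2.06 (camera adjusted p = 1.88e-13, 0.234 estimated). Of matrix genes, 3 of 30 members rose and 26 fell (3 and 26 adjusted over the list alone), with Col6a1 (-2.62) and Col6a2 (-2.80). For matrix genes the median was -1.72 (camera adjusted p = 1.05e-12, 0.509 estimated). Of genes of mesenchymal transition, 18 of 18 members fell (18 adjusted over the list alone), with Sparc (-2.11 ± 0.15) and the transcription factor Prrx1 (-1.98 ± 0.18). Mesenchymal transition genes had a median of -1.13 (camera adjusted p = 3.06e-09, 0.234 estimated). Of TGF-beta genes, 9 of 17 members fell (10 adjusted over the list alone), including Tgfb1 (-0.89) and Tgfbr2 (-0.74). TGF-beta genes had a median of -0.29 (camera adjusted p = 0.00404, 0.509 estimated). Of endothelial markers, 2 of 26 members rose and 19 fell (2 and 19 adjusted over the list alone), for example Cldn5 (-1.07) and Esam (-0.81). For endothelial markers the median was -0.54 (camera adjusted p = 0.00472, 0.754 estimated). Of pericyte and smooth muscle markers, 10 of 13 members fell (10 adjusted over the list alone), for example Cnn1 (-2.22) and Acta2 (-1.51). Pericyte markers had a median of -0.77 (camera adjusted p = 0.00731, 0.547 estimated). Of lymphatic markers, 5 of 7 members fell (5 adjusted over the list alone), for example Sema3d (-1.80) and Thy1 (-0.96). Lymphatic markers had a median of -0.91 (camera adjusted p = 0.0358, 0.509 estimated). Of complement genes, 12 of 17 members fell (12 adjusted over the list alone), for example Cd55 (-1.35) and C1s1 (-1.65). For complement genes the median was -1.03 (camera adjusted p = 0.00188, 0.693 estimated). Of monocyte genes, 1 of 14 members rose and 10 fell (1 and 11 adjusted over the list alone), for example Fn1 (-1.45) and F13a1 (-1.36). Monocyte genes had a median of -1.02 (camera adjusted p = 0.0106, 0.526 estimated). The muscle markers went from 1.86% ± 1.13 (n = 10) to 0.336% ± 0.273 of reads (n = 9), and 6 of the 20 muscle list members fell (1 adjusted over the list alone, median -2.60, camera adjusted p = 0.0661). Without the skin-high libraries 18 of them fell, as did 18 among muscle-limited libraries, and camera called the list under 8 alternatives. With the muscle score as a covariate, 5920 of the 7011 genes (84.4%) kept their call and sign. The endothelial, pericyte and lymphatic calls ended with the digits as a term, and the lymphatic call also with the filter at 5 CPM (camera adjusted p up to 0.597, 0.142 and 0.184 over the alternatives).

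Epithelial and lymphoid lists in FL-HER2 tumors were called in both directions. Of basal and myoepithelial markers, 1 of 14 members rose and 10 fell (1 and 10 adjusted over the list alone), with the keratin Krt14 (-3.25 ± 0.18) and the basal lineage factor Trp63 (-3.20 ± 0.18) falling. Basal markers had a median of -1.96 (camera adjusted p = 1.14e-05, 0.234 estimated). The skin list went from 156 ± 201 (n = 10) to 44.9 ± 8.88 CPM (n = 9), 3 of its 7 members fell (3 adjusted over the list alone, median -0.83, camera adjusted p = 0.134), and camera called it under 4 alternatives. Without the skin-high libraries 10 basal members fell and 1 rose (median -1.80). Of hypoxia genes, 2 of 23 members rose and 17 fell (2 and 17 adjusted over the list alone), for example the collagen hydroxylases P4ha2 (-0.90) and P4ha1 (-0.76). For hypoxia genes the median was -0.43 (camera adjusted p = 0.00490, 0.693 estimated). Of Wnt targets, 3 of 15 members rose and 10 fell (4 and 10 adjusted over the list alone), with Lgr5 (-2.22) and Notum (-3.24). Wnt targets had a median of -0.82 (camera adjusted p = 0.0254, 0.564 estimated). Of proliferation genes, 24 of 30 members rose (25 adjusted over the list alone), such as the replication helicase subunits Mcm6 (0.48 ± 0.06) and Mcm3 (0.39 ± 0.05) and the mitotic gene Birc5 (0.43 ± 0.07). Proliferation genes had a median of 0.26 (camera adjusted p = 4.55e-07, 0.526 estimated). Of MYC targets, 10 of 20 members rose and 1 fell (10 and 1 adjusted over the list alone), such as Nop58 (0.34) and Pa2g4 (0.26). For MYC targets the median was 0.13 (camera adjusted p = 0.00731, 0.564 estimated). Of p53 targets, 10 of 20 members rose and 4 fell (10 and 4 adjusted over the list alone), with Trp53inp1 (0.64) rising and Perp (-1.03) falling. Targets of p53 had a median of 0.16 (camera adjusted p = 0.0339, 0.509 estimated). Of ribosomal protein genes, 5 of 24 members rose (1 adjusted over the list alone), led by Rpl7 (0.19) and Rps18 (0.13), and the call of Rps18 ended without any of 4 libraries (adjusted p up to 0.0700). Ribosomal protein genes had a median of 0.08 (camera adjusted p = 0.0418, 0.796 estimated). Of T cell genes, 13 of 21 members rose and 2 fell (14 and 2 adjusted over the list alone): Cd4 (1.18 ± 0.28) and Cd6 (1.76 ± 0.42) rose, and Thy1 (-0.96 ± 0.14) and Lef1 (-0.82 ± 0.17), which other cells of the tumor can express, fell. For T cell genes the median was 1.21 (camera adjusted p = 0.0107, 0.757 estimated). Of MHC class II genes, 6 of 9 members rose (7 adjusted over the list alone), for example H2-eb1 (1.25) and H2-aa (1.09). MHC class II genes had a median of 0.87 (camera adjusted p = 0.0136, 0.714 estimated). The T cell list had a median of -0.10 when only genes with at least 5 CPM in 9 libraries were tested (camera adjusted p 0.000540 to 0.808 over the alternatives, the highest there), and the Wnt call ended under that filter and with the digits as a term (0.00386 to 0.208). The p53 call ended after quantile normalization (0.0145 to 0.0595), and the MHC class II and ribosomal calls each ended under 3 alternatives (0.000592 to 0.157 and 6.99e-08 to 0.418).

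In p95HER2 tumors, day 22 was compared with day 10 in the same way. By camera with its preset correlation the matrix, mesenchymal, fibroblast, basal, TGF-beta and cholesterol synthesis lists were lower at day 22, and the proliferation list, of which 9 of 30 members rose, was higher. None of these calls held with an estimated correlation (adjusted p of at least 0.170). Dcpp3 (5.26 ± 0.54, adjusted p = 4.29e-10) and Dcpp1 (5.10 ± 0.47, 2.66e-11) again had the largest rises, then the cation channel Trpm3 (4.14 ± 0.41, 1.33e-10), the cartilage gene Cnmd (3.15 ± 0.32, 3.32e-10) and Susd5 (3.01 ± 0.27, 1.23e-11). The largest falls were in Tnn, from 11.9 ± 10.4 to 0.731 ± 0.787 CPM (-3.84 ± 0.49, 4.69e-08), the retinol transporter Stra6 (-3.36 ± 0.25, 9.28e-14), the cadherin Cdh15 (-3.08 ± 0.36, 5.83e-09), the proteoglycan Acan (-2.90 ± 0.28, 1.28e-10) and the transcription factor Foxq1 (-2.89 ± 0.22, 1.82e-13). In all, 4799 genes (35.2%) changed, 2262 higher and 2537 lower at day 22, and 670 by at least 2-fold (216 higher, 454 lower). Of the calls 47.1% were higher on the deposited values and 64.3% on log2(CPM + 1), and 3167 genes were called among muscle-limited libraries, where 13 of 20 muscle list members fell (median -1.26).

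Of matrix genes in p95HER2 tumors, 1 of 30 members rose and 24 fell (1 and 24 adjusted over the list alone), with Col6a1 (-1.99 ± 0.16) and Col6a2 (-2.005 ± 0.17). Matrix genes had a median of -1.03 (camera adjusted p = 1.87e-11, 0.673 estimated). Of mesenchymal transition genes, 17 of 18 members fell (18 adjusted over the list alone), with Tnc (-1.76) and Fn1 (-1.07). For mesenchymal transition genes the median was -0.87 (camera adjusted p = 9.58e-10, 0.170 estimated). Of fibroblast markers, 18 of 24 members fell (18 adjusted over the list alone), with Col1a1 (-2.02) and Postn (-1.55). Fibroblast markers had a median of -0.81 (camera adjusted p = 2.97e-08, 0.673 estimated). Of basal and myoepithelial markers, 12 of 14 members fell (12 adjusted over the list alone), with Trp63 (-2.47 ± 0.18) and Krt14 (-2.20 ± 0.18). Basal markers had a median of -1.37 (camera adjusted p = 5.46e-08, 0.170 estimated). The skin list went from 154 ± 165 to 73.3 ± 48.7 CPM (n = 10 each), with 1 of 7 members lower (median -0.65, camera adjusted p = 0.506), and 11 basal members fell without the skin-high libraries (median -1.39). Of TGF-beta genes, 14 of 17 members fell (14 adjusted over the list alone), with Inhba (-1.79) and Tgfb1 (-0.80). For TGF-beta genes the median was -0.28 (camera adjusted p = 5.67e-06, 0.170 estimated). Of cholesterol synthesis genes, 17 of 23 members fell (1 higher and 20 lower adjusted over the list alone), among them Msmo1 (-0.94 ± 0.11) and Cyp51 (-0.76 ± 0.10). Cholesterol synthesis genes had a median of -0.39 (camera adjusted p = 4.52e-08, 0.700 estimated). Of proliferation genes, 9 of 30 members rose (8 adjusted over the list alone), with Mcm3 (0.41) and Mcm6 (0.46). Proliferation genes had a median of 0.11 (camera adjusted p = 0.00160, 0.966 estimated). The muscle markers took 0.316% ± 0.407 of reads at day 10 and 0.207% ± 0.200 at day 22 (n = 10 each), and 4794 of the 4799 genes (99.9%) kept their call and sign with the muscle score as a covariate.

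The time effects in the 2 constructs, which share no library, overlapped as well. Genes higher at day 22 in both numbered 1271 (469 if the calls were independent) and genes lower in both 1808 (777), against 42 and 103 that went opposite ways (526 and 693).

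Finally, the difference between the constructs was tested for a change between days, as the p95HER2 effect at day 22 minus that at day 10. Stromal, vascular and complement genes, which were lower in p95HER2 at day 10, had effects nearer to 0 or above it at day 22. Camera with its preset correlation called these lists positive and the T cell list negative, and with an estimated correlation it called none of them. The largest positive values belonged to genes of striated muscle: the cytochrome oxidase isoforms Cox8b (3.45 ± 1.25, adjusted p = 0.0466) and Cox7a1 (2.84 ± 0.67, 0.00283), Popdc2 (3.13 ± 1.03, 0.0293), cardiac actin Actc1 (3.03 ± 1.04, 0.0358) and the glucose transporter Slc2a4 (3.01 ± 1.03, 0.0357). The largest negative values were those of Stra6 (-2.89 ± 0.35, 9.63e-07), Otof (-2.64 ± 0.55, 0.000988), the cytokine receptor Il18rap (-1.90 ± 0.36, 0.000377), Mmp10 (-1.87 ± 0.62, 0.0290) and Acap1 (-1.71 ± 0.27, 5.52e-05). In all, 2682 genes (19.6%) passed, 1836 positive and 846 negative, and 567 by at least 1 on the log2 scale (510 positive, 57 negative). The positive share was 68.5% on the deposited values, 56.7% with median-of-ratios size factors, 43.5% after quantile normalization and 56.1% on log2(CPM + 1). Leaving out 1 library ended the call of Cox8b for 27 libraries, Actc1 for 11 and Slc2a4 for 11, and that of Mmp10 without FL-HER2 day 22 replicate 6 (adjusted p = 0.0506). With the muscle score as a covariate, 1981 of the 2682 genes (73.9%) kept their call and sign, and without the 11 skin-high libraries 1659 genes passed. With library weights 4577 passed, with the digits as a term 233, and among muscle-limited libraries 153.

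Camera called 23 lists in this test, and all gave adjusted p of at least 0.644 with an estimated correlation. Of endothelial markers, 17 of 26 members were positive and 1 negative (17 and 1 adjusted over the list alone), with Esam (1.01 ± 0.18) and Eng (0.95 ± 0.18). For endothelial markers the median was 0.78 (camera adjusted p = 4.88e-07, 0.644 estimated). Of fibroblast markers, 13 of 24 members were positive (17 adjusted over the list alone), with Cd34 (1.36) and Ogn (1.83). Fibroblast markers had a median of 1.01 (camera adjusted p = 8.34e-07, 0.644 estimated). Of matrix genes, 19 of 30 members were positive and 1 negative (21 and 2 adjusted over the list alone), with Sparc (1.13) positive and Lamb1 (-0.57) negative. Matrix genes had a median of 0.73 (camera adjusted p = 0.000245, 0.650 estimated). Of pericyte and smooth muscle markers, 4 of 13 members were positive (4 adjusted over the list alone), with Abcc9 (1.33) and Rgs5 (1.17). For pericyte markers the median was 0.49 (camera adjusted p = 0.0140, 0.644 estimated). Of complement genes, 7 of 17 members were positive (9 adjusted over the list alone), with Cd55 (1.32) and Clu (1.25). Complement genes had a median of 0.65 (camera adjusted p = 0.000824, 0.644 estimated). Of cholesterol synthesis genes, 6 of 23 members were negative (9 adjusted over the list alone), with Hsd17b7 (-0.63). Cholesterol synthesis genes had a median of -0.32 (camera adjusted p = 5.31e-06, 0.644 estimated). Of T cell genes, 3 of 21 members were negative (3 adjusted over the list alone), with Tcf7 (-0.43) and Bcl11b (-1.32). For T cell genes the median was -1.14 (camera adjusted p = 0.000247, 0.644 estimated). The muscle list had a median of 2.59 (camera adjusted p = 0.0232, adjusted p = 0.737 with an estimated correlation), a call that ended under 3 alternatives (0.000530 to 0.580), and its share of reads was 1.86% ± 1.13 in FL-HER2 at day 10 against 0.207% to 0.336% on average in the other 3 groups. The T cell call ended with the filter at 5 CPM and the complement call among muscle-limited libraries (camera adjusted p 6.33e-07 to 0.200 and 2.00e-05 to 0.243 over the alternatives). The fibroblast, matrix and pericyte calls ended with the digits as a term (4.70e-09 to 0.0539, 1.85e-06 to 0.650 and 0.00238 to 0.370). In the muscle-limited libraries 19 of the 23 genes named in this test did not pass, and 18 did not under at least 1 other alternative.

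**Figure D4:**
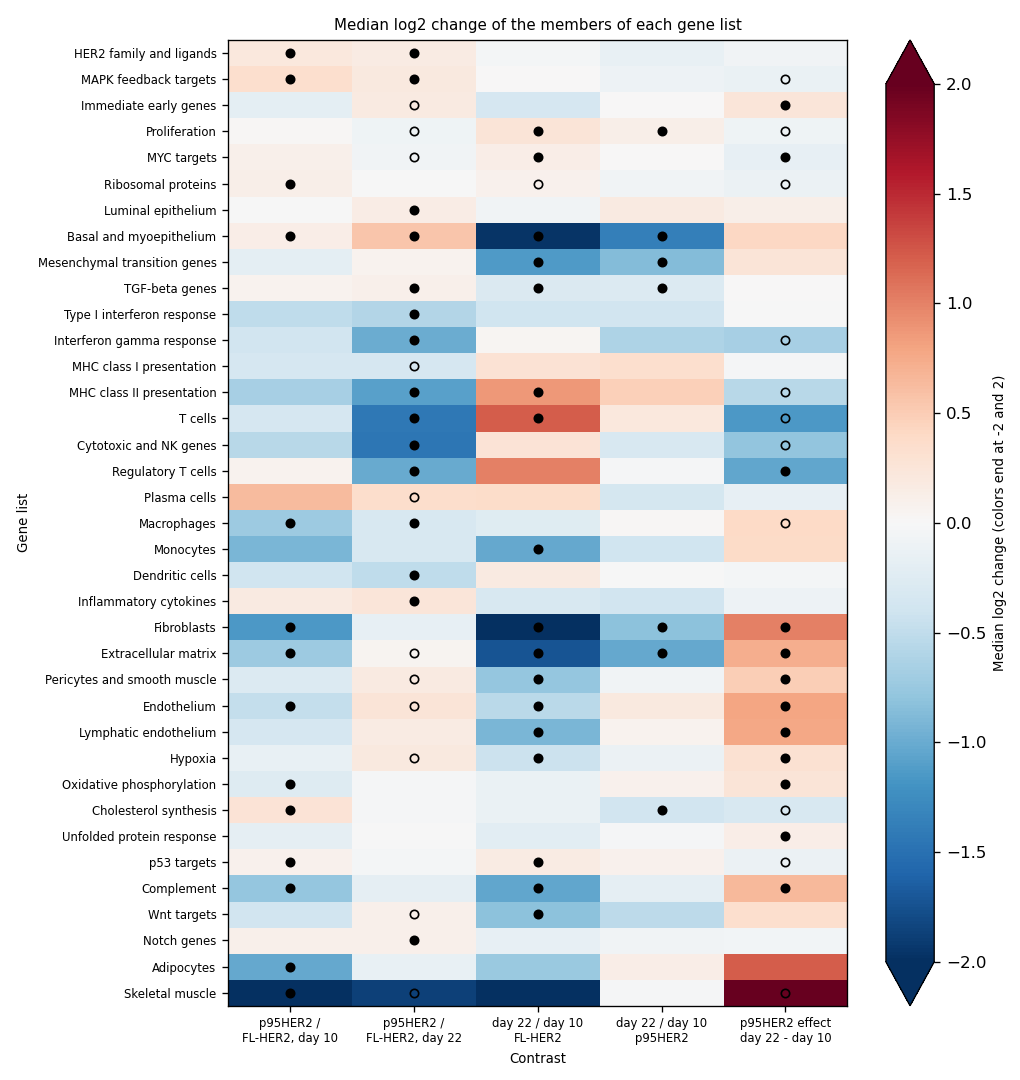
Median log2 change of the members of the 37 gene lists that camera called in at least 1 of the 5 contrasts (columns), with colors that end at -2 and 2. Filled dots mark camera calls whose mean list score also passed the permutation test, and open dots camera calls that did not. The fibroblast list is at -1.14, -0.16, -2.06, -0.81 and 1.01 from left to right.

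Across the 51 lists tested, camera with its preset correlation called 14 at day 10, 26 at day 22, 18 with time in FL-HER2, 7 with time in p95HER2 and 23 for the change between days. With an estimated correlation, the MAPK feedback list at day 10 and the basal, MAPK feedback and HER2 family lists at day 22 kept their calls.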

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

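The tests of a lower share of host cells at either day, of lymph node tissue and of construct reads were chosen after the results were seen. So were the muscle score covariate, the muscle-limited libraries and the digits term.

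Fibroblast, macrophage, endothelial and oxidative phosphorylation scores were lower in p95HER2 tumors at day 10, where the muscle share of reads also differed. With the muscle score of each library as a covariate, the differences were -0.995 for fibroblasts (95% interval -1.35 to -0.638; -1.10 without it), -0.548 for macrophages (-0.790 to -0.305; -0.744 without), -0.454 for endothelium (-0.740 to -0.169; -0.477 without) and -0.182 for oxidative phosphorylation (-0.294 to -0.0694; -0.278 without), which argues against muscle as the whole cause. A lower share of all host cells alone would lower fibroblast and endothelial scores alike. The fibroblast score fell by a further -0.627 (-0.859 to -0.394), which leaves such a share open as a part. Muscle stays open as a part of the cause for all 4. In muscle-limited libraries, which are not matched in muscle, their medians were -0.79, -0.48, -0.32 and -0.12 in that order. Camera no longer called the last 2 there, so the 2 checks differ for these. A difference tied to the 5-digit numbers of 8 FL-HER2 libraries stays open too. With the digits as a term the medians were -0.56, -0.58, -0.11 and -0.16, and only the endothelial call ended. That p95HER2 tumors held fewer fibroblasts and macrophages at day 10 remains a hypothesis.

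The T cell score was lower in p95HER2 tumors at day 22 by -1.24 (95% interval -1.90 to -0.583), and with the muscle score as a covariate by -1.04 (-1.67 to -0.405), which argues against muscle tissue as its cause. The endothelial score was higher in p95HER2 by 0.249 (0.00604 to 0.492) and the fibroblast score differed by -0.204 (-0.512 to 0.105), which argues against a lower share of all host cells. Lymph node tissue in the FL-HER2 tumors cannot be told apart: the log2 summed counts of the B cell list differed by -0.376 (-0.671 to -0.0809), and the interval spans the bound set for that explanation. The B cell genes summed to 8.52 ± 1.17 CPM in FL-HER2 (SD, n = 9) and 6.66 ± 1.47 CPM in p95HER2 (n = 10). A smaller T cell infiltrate in p95HER2 tumors at day 22 is a candidate explanation that stays open beside it.

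Erbb2 was higher in p95HER2 tumors at both times. After adding the muscle score as a covariate the differences were 0.698 (95% interval 0.449 to 0.947) at day 10 and 0.666 (0.444 to 0.888) at day 22. Both thus remained with this term, which leaves muscle open as a part of the cause. A gain of the surrounding region would raise neighboring genes, but the 28 other tested genes within 500 kb had a median log2 difference of -0.0437 at day 10 and 0.0499 at day 22. Reads of the construct counted as Erbb2 cannot be told apart from those of the endogenous gene, since the table holds 1 value per gene for the difference of 0.845 at day 10, and the species and length of each construct could change that value.

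In each comparison, 100 splits of the libraries were fitted and 1, the real one, called as many genes, so that chance can be excluded at the level of 1 in 100 if these libraries are independent samples, which the labels do not say. The real and the highest other counts were 5636 and 1836 at day 10, 617 and 21 at day 22, 7011 and 4183 with time in FL-HER2, 4799 and 236 with time in p95HER2, and 2682 and 1732 for the change between days.

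In 23 of 187 groups of values 1 library lay far from the others, where chance gives about 1 in 20 groups. The muscle list took 0.935% of reads in FL-HER2 day 22 replicate 8 (0.0280% to 0.479% in the rest of its group). Rn45s, a ribosomal RNA precursor, took 6.40% in FL-HER2 day 22 replicate 4 (0.294% to 2.42% in the rest) and 1.27% in p95HER2 day 10 replicate 5 (0.271% to 0.560%). FL-HER2 day 10 replicate 10 was low in 11 muscle-linked genes, with log2 values of 6.45 for Myh7, 10.55 for Myh4, 10.12 for Ckm, 5.34 for Ckmt2, 8.22 for Pvalb, 4.77 for Cdh15, 4.98 for Cox8b, 3.60 for Popdc2, 3.89 for Actc1, 5.55 for Slc2a4 and 4.74 for Cox7a1. FL-HER2 day 22 replicate 7 was low in Myh7 (0), Myh4 (9.46), Pvalb (5.19) and Slc2a4 (2.99), and replicate 8 of that group was high in Cox7a1 (7.48). Away from muscle, Ly6i was at 0.82 in p95HER2 day 22 replicate 1, Trpm3 at 0 in p95HER2 day 10 replicate 5, and Stra6 at 6.28 in p95HER2 day 10 replicate 6 and 5.27 in p95HER2 day 22 replicate 3.

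The p95HER2 effect differed between days for 16 of the 44 genes named for the largest changes or in every comparison. Beside the 10 named for that test (Cox8b 3.45, Popdc2 3.13, Actc1 3.03, Slc2a4 3.01, Cox7a1 2.84, Stra6 -2.89, Otof -2.64, Il18rap -1.90, Mmp10 -1.87 and Acap1 -1.71) these were Wfdc12 (2.77), Krt6a (2.65), Dlk1 (2.43), Chad (2.27), Cnmd (1.65) and Lama3 (0.63). Of gene lists, 23 did so by camera with its preset correlation, and 0 with an estimated one (0 also at an unadjusted p under 0.05), while 12 of the 23 also passed the permutation test and fry called 21 lists. Positive medians were those of skeletal muscle (2.59), fibroblasts (1.01), endothelium (0.78), lymphatic endothelium (0.77), matrix (0.73), complement (0.65), pericytes (0.49), macrophages (0.40), hypoxia (0.31), oxidative phosphorylation (0.26), immediate early genes (0.25) and the unfolded protein response (0.14). Negative medians were those of T cells (-1.14), regulatory T cells (-1.04), cytotoxic genes (-0.79), the interferon gamma response (-0.66), MHC class II (-0.56), cholesterol synthesis (-0.32), MYC targets (-0.16), MAPK feedback (-0.14), ribosomal proteins (-0.12), p53 targets (-0.12) and proliferation (-0.0871).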

How the results depend on the processing

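The muscle covariate, muscle range, skin limit, digits term, log2(CPM + 1), voom and the permutation of list scores were chosen after seeing the data. The other alternatives were chosen before. Pseudocounts of 0.1 and 5, both filters, median-of-ratios and quantile scaling, log2(CPM + 1), voom and the fit on only the groups compared left each count of genes called within 1.5 times its value. With library weights the count rose to 1418 at day 22, 4577 for the change between days and 626 for the overlap of 308 genes called the same way at both times. The rank-sum test called 267 genes at day 22, an overlap of 133. The muscle score as a covariate left 3242 genes called at day 10. Among muscle-limited libraries, which are fewer, 641, 252, 3506, 3167 and 153 genes were called at day 10, at day 22, with time in FL-HER2, with time in p95HER2 and for the change between days, with an overlap of 85. Without the 11 libraries high in skin markers 3988, 228, 6915, 3508 and 1659 genes were called in that order, with an overlap of 124. With the digits as a term, which leaves the FL-HER2 level at day 10 to 2 libraries, these were 1375, 663, 2953, 4875 and 233, and the overlap 170. In the same order, 1010, 128, 1445, 670 and 567 genes had a log2 change of at least 1. Where no reason is given, the cause was not tested.

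Without 1 library, the counts ran from 5003 to 5965 at day 10, 339 to 892 at day 22, 6586 to 7219 and 4443 to 4898 with time in FL-HER2 and p95HER2, 2233 to 3233 for the change between days and 206 to 412 for the overlap. Erbb2 ran from 0.79 to 0.90 at day 10, 0.69 to 0.80 at day 22, -0.91 to -0.79 and -1.01 to -0.91 with time, and -0.17 to -0.05 for the change between days, which was 0.0298 in the muscle range and 0.0560 without skin-high libraries. No paired analysis was possible because the labels share no tumor number between groups.

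Camera called 23 lists at day 10 and 28 with time in FL-HER2 without a filter, and 12 with time in p95HER2 on log2(CPM + 1). With an estimated correlation it called 1 at day 10, 3 at day 22 and 0 in the other comparisons (3, 3 and 0 at an unadjusted p under 0.05). Fry called 29, 12, 33 and 16, and 21 for the change between days. The permutation test called 30, 15, 37, 14 and 15.

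The T cell list with time in FL-HER2 was at -0.10 with the filter at 5 CPM, which leaves fewer of its genes. Atp5b with time in FL-HER2 was at 0.0231 after quantile normalization, a cause not tested. With the muscle score as a covariate, which holds the same genes, the muscle list was at -0.0106 at day 10, 0.0283 at day 22 and 0.00561 for the change between days, and Myh7 (0.18), Pvalb (0.11) and Des (0.0521) turned at day 10. In the muscle range the muscle list was at 0.0738 at day 22 and Des at 0.00215 at day 10. There the medians of the HER2 family list at day 10 (-0.12) and of the MAPK feedback list for the change between days (0.0267) turned too, while camera's direction for them did not. With the digits as a term Stab1 (0.16) and Clec4d (0.0978) turned at day 10, Psmb8 (-0.0560), Nlrc5 (-0.45), H2-q4 (-0.17), H2-k1 (-0.17) and G0s2 (0.0707) with time in FL-HER2. Camera's direction turned for the matrix list at day 10 (median -0.0827) and for the change between days (0.20), and for the interferon gamma list with time in FL-HER2 (-1.45) and for the change between days (0.78). Of single genes examined over the 5 comparisons, 761 results were as before and 44 lost a call with quantile scaling, 724 and 75 with the covariate, 586 and 65 with the rank-sum test, 465 and 345 in the muscle range, 684 and 125 under the limit on skin markers, and 536 and 269 with the digits as a term.

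Depth limits little above 1 CPM, as 1 CPM is at least 21.8 reads here, and the spread between libraries limits small effects. The planned count tests were not run.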

Other observations

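The restriction to muscle-limited libraries and the digits term were chosen after the results were seen.

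Several immune and signaling lists without a camera call on the deposited values had members that differed between constructs at day 10. Of all 13650 tested genes 2071 rose and 3565 fell there, so such counts alone show no move of a list. Under other settings camera called the inflammatory cytokine and TGF-beta lists in 5 cases each, the monocyte and chemokine lists in 6, the type I interferon list in 7 and MYC targets in 9. Of type I interferon genes, 4 of 26 members fell (0 adjusted over the list alone, median -0.51), and with the digits as a term 23 (median -1.74), while camera then also called the interferon gamma (1 member lower, -1.82) and MHC class I lists (5 members lower, -1.28). Of MYC targets, 3 of 20 members rose and 1 fell (3 and 1 adjusted over the list alone). Of inflammatory cytokine genes, 6 of 15 members rose in p95HER2 and 3 fell (6 and 3 adjusted over the list alone). Il23a, a subunit of IL-23, went from 0.175 ± 0.0792 to 2.31 ± 0.660 CPM (SD, n = 10 each, log2 change 3.48 ± 0.28) and Il1a from 0.237 ± 0.182 to 2.67 ± 0.963 CPM (3.43 ± 0.32), while Il18 fell (-1.07 ± 0.17). The rises were smaller at day 22, with a change between days of -1.87 ± 0.40 for Il23a and -2.13 ± 0.46 for Il1a, both past the test. Of monocyte genes, 3 of 14 members rose and 9 fell (3 and 9 adjusted over the list alone), with the chemokine receptor Ccr2 (-1.30 ± 0.17) and the integrin Itgam (-1.08 ± 0.16) among the falls. Of chemokines, 1 of 23 members rose and 10 fell (1 and 10 adjusted over the list alone), among them Cxcl12 (-0.82 ± 0.15) and Ccl2 (-1.55 ± 0.29). In the TGF-beta list 6 of 17 members rose and 2 fell (6 and 2 adjusted over the list alone), with Inhba (1.62 ± 0.16) and the SMAD corepressor Skil (0.47 ± 0.06) higher. Of NRF2 targets, 2 of 19 members rose and 9 fell (3 and 10 adjusted over the list alone), such as the glutathione transferases Gstm2 (-1.52 ± 0.21) and Gstm1 (-1.52 ± 0.23). Muscle markers took 1.86% of reads in these FL-HER2 tumors and 0.316% in p95HER2. Among the muscle-limited libraries, the calls of Itgam (-0.77), Cxcl12 (-0.75), Gstm2 (-0.87) and Gstm1 (-0.90) ended, as did that of Il1a for the change between days (-2.16). With the digits as a term the calls of Skil (0.29) and Cxcl12 (-0.50) ended, and that of Il1a for the change between days (-1.26).

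Checkpoint genes moved both ways between the constructs. In p95HER2 tumors 4 of 19 members were higher and 3 lower at day 10 (4 and 3 adjusted over the list alone), and 2 higher and 3 lower at day 22 (3 and 6), where camera called the list under 6 alternatives. Nt5e, the CD73 ectoenzyme that makes adenosine, was higher in p95HER2 at both times (0.94 ± 0.13 and 1.19 ± 0.14) and fell with time in both constructs (-1.68 ± 0.14 in FL-HER2 and -1.44 ± 0.13 in p95HER2). Of chemokines at day 22, 2 of 23 members rose and 1 fell (3 and 4 adjusted over the list alone), and camera called the list under 1 alternative: Cxcl5, which attracts neutrophils (2.84 ± 0.42), and Cxcl15 (3.61 ± 0.53) rose. For the change between days the value of Cxcl15 was 4.51 ± 0.74.

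With time, regulatory T cell and luminal genes changed without a camera call on the deposited values, though camera called the regulatory T cell list in FL-HER2 under 3 alternatives and that of the unfolded protein response under 3. In FL-HER2 tumors 7 of 9 tested regulatory T cell members rose and 1 fell (7 and 1 adjusted over the list alone). Foxp3 went from 0.505 ± 0.179 to 2.17 ± 0.875 CPM there (1.87 ± 0.30) and was at 0.602 ± 0.298 and 0.674 ± 0.335 CPM in p95HER2, a change between days of -1.77 ± 0.42 that passed the test but not in the muscle-limited libraries (-1.28) or with the digits as a term (-1.67). Of luminal markers, 6 of 20 members rose and 7 fell in FL-HER2 (6 and 8 adjusted over the list alone), and 6 rose and 6 fell in p95HER2 (7 and 7). Krt7 fell in both constructs (-2.31 ± 0.16 and -2.12 ± 0.16), and the transcription factor Tfap2c rose in both (0.69 ± 0.07 and 0.64 ± 0.07). Of HER2 family genes and ligands, 2 of 12 members rose and 5 fell in FL-HER2 (2 and 5 adjusted over the list alone), as they did in p95HER2 (3 and 6). The ligand Nrg2 rose (1.10 and 1.18) and Nrg1 fell (-1.72 and -1.26) in FL-HER2 and p95HER2. Of unfolded protein response genes in FL-HER2, 1 of 20 members rose and 13 fell (1 and 13 adjusted over the list alone), with Trib3 (-0.68 ± 0.08) and Xbp1 (-0.57 ± 0.08, a call that ended with the digits as a term at -0.36). In the Notch list in p95HER2, 2 of 13 members rose and 5 fell (2 and 5 adjusted over the list alone), Jag1 among them (-1.40 ± 0.12).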
